A study of Mus musculus with 20 samples.

How the data were processed

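ChIP-seq of Bcl11b and Foxp3 was deposited for 20 samples in 9 groups, 12 immunoprecipitated and 8 input libraries from sorted mouse CD4+ T cells. Per the submitters' processing notes, the tools were FastQC, Trim Galore 0.4.2, cutadapt 1.12, HISAT2 2.1.0, SAMtools 1.3, HOMER 4.10.1 and deepTools, with mm10 as the genome build; the notes give the names without roles or settings. The authors deposited 12 lists of regions, each with the 3 columns chromosome, start and end and no header. They hold positions only, so no unit of signal, score or p-value enters. The rule that put a region in a specific or common list, the threshold of the peak calls and whether replicates were pooled are not given in the sources used here. The lists are per group, so no value per replicate was analysed here and the depth of each library is unknown; intervals cover counting error only. The description of the third Treg Bcl11b replicate names none of the lists, and that of the second WT Foxp3 replicate leaves out the list common to Bcl11b and Foxp3, so it is open whether they entered.

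All 12 lists draw on 1 set of 22081 regions. Each set has a modal width, of 198 bp for Treg Bcl11b, 226 bp for Tn, 252 bp for KIKO, 220 bp for WT Foxp3 and 276 bp for Bcl11b-KO Foxp3. Common lists also hold regions of exactly such a width, for example 2493 of 220 bp and 3180 of 276 bp in the comparison of WT and Bcl11b-KO Foxp3, so it is open whether common means a peak called in both sets. Rows that repeated a region, 127 in all, were dropped. A further 25 regions stood in 2 classes of 1 comparison, 4 with Tn, 4 with KIKO and 17 with Bcl11b-KO, and were left out of that comparison, a choice made after the lists were seen. The Treg Bcl11b side differs between comparisons, with 6518 regions against Tn, 5646 against KIKO and 7235 against Foxp3, 5181 of them in all 3. WT Foxp3 has 14250 and 15365, with 13387 in both.

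Regions of different lists were matched by identity, which equals an overlap of at least 1 bp because no regions overlap. Shares have Wilson 95% intervals. Cross-classifications used Fisher's exact test, two-sided, with the conditional odds ratio and its exact 95% interval. Cross-classifications cover the regions that are listed in both comparisons. Chance overlap came from 1000 circular shifts within chromosomes. Gene names and positions came from a RefSeq table of GRCm38.p6, the assembly with the coordinates of mm10, with 21883 protein-coding genes. The table gives the ends of genes without strand, so a start site could not be named. In place of the planned nearest transcription start, a region was assigned to the protein-coding gene nearest its centre, at distance 0 inside a gene and at most 100 kb away, and promoter share was replaced by the share of centres within 1 kb of either gene end. This placed 21848 regions (98.9%) at 11004 genes. Exons, introns and UTRs were not used here.

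The 12 gene lists and the rule for named genes were fixed before the data were examined. Always named are Foxp3, Il2ra, Ctla4, Ikzf2, Ikzf4, Il10, Bcl11b, Satb1, Gata3, Ifng and Il17a. To these come the 5 genes with the most regions of each class (ties by symbol, predicted genes passed over) and up to 4 members of each list with an adjusted p under 0.05. The lists are the Treg signature, suppressive mediators and inhibitory receptors, T helper effector, naive and T lineage, TCR signalling, chemokine receptors and homing, IL-2 and STAT5, housekeeping, B cell markers, myeloid markers, CD8 and NK markers, and neural genes. Some genes that the rule names are not reported here. Some genes stand on more than 1 list. Occupancy is the number of list genes with a region, set against 10000 random lists matched in 10 groups on the genome length nearest each gene, with a two-sided permutation p. Share by class compares the regions at list genes between a specific and the common list with a two-sided Fisher's exact test. Both were adjusted by Benjamini-Hochberg, over 60 and 96 tests, as were the gene end shares. Regions at 1 gene are not independent of each other, so these p-values can be too small.

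The steps were tested on simulated data. Gene assignment matched a plain search at 2400 of 2400 cases. With the sizes of the KIKO by Foxp3 table, a planted odds ratio of 0.5 lay inside its interval in 289 of 300 draws, and with no effect 10 of 300 draws had p under 0.05. Over simulated region sets on the protein-coding genes, occupancy called 94 of 100 lists with 5-fold odds and 5 of 100 without effect. With the list sizes of the Bcl11b-KO comparison, share by class called 200 of 200 planted lists with 5-fold odds and 6 of 1720 others. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

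Alternatives were overlap within 100 bp of centres or 500 bp of edges, autosomes only, regions over 1 kb from a gene end, 2.5 kb from a gene end, ends of any annotated gene, assignment within 20 kb or to gene bodies with 10 kb on each side, and Fisher's exact test without matching. Added after the lists were seen were repeated rows kept, common regions of a single-set width left out, regions wider than 276 bp, regions common with Tn or KIKO, the nearest gene end, lists over regions far from gene ends, and the 2 specific lists of a comparison set against each other. Of the explanations set down for testing, those for Treg specificity (near gene ends, called in 1 set) and nearness to gene ends for loss are given as alternatives, with odds ratios of 0.0944, 0.330 and 0.379; the test of Foxp3 at the same site was widened to regions common with Tn after its first result was seen. The 10 motifs fixed in advance were not tested, since no genome sequence was used here, and tests on peak scores were not run because the lists hold none.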

Results

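Bcl11b is a zinc-finger transcription factor of the T lineage, and Foxp3 is the transcription factor that defines regulatory T cells (Treg). The series mapped where the 2 proteins bind in mouse T cells by chromatin immunoprecipitation and sequencing (ChIP-seq). Bcl11b was precipitated from wild-type (WT) Treg cells in 3 libraries, from WT cells labelled Tn in 3 libraries, and in 2 libraries from KIKO cells, which are Treg cells that lack Foxp3. Foxp3 was precipitated from WT Treg cells in 2 libraries and from Treg cells without Bcl11b (Bcl11b-KO) in 2 libraries. A further 8 libraries were input DNA, which makes 20 samples in 9 groups. The labels do not expand Tn and give the Tn cells the same sort markers as the Treg cells, so the name is used as labelled.

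The data are 12 lists of genomic regions in mm10, 3 for each of 4 pairwise comparisons. In each comparison a region is listed as specific to the first set, common, or specific to the second set. The lists hold 22081 distinct regions, none of which overlaps another. Of these, 37.9% lay within 1 kb of an end of a protein-coding gene, against a mean of 3.20% and a maximum of 4.16% over 100 circular shifts of the regions along the chromosomes. Centres of 13335 regions (60.4%) fell inside a protein-coding gene. The lists give no score, read count or replicate value, so the read depth behind each call is unknown. Intervals of shares are Wilson 95% intervals and cover counting error only, and each p compares the regions of these lists, not the conditions. The labels do not say that the replicates came from separate animals. Below, a region is called lost where the list places it in the class specific to the WT cells.

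The comparison of Treg and Tn cells asks which Bcl11b sites belong to Treg cells. Most Bcl11b regions were listed in both. Of the 6518 regions on the Treg side, 4493 (68.9%, 67.8 to 70.0) were common and 2025 were Treg-specific, while 725 were Tn-specific. The single region in Foxp3, at 7583933 to 7584227 of chromosome X, was Treg-specific. So were the single regions of Ctla4, which encodes an inhibitory receptor, of Ikzf4, a transcription factor gene of the Ikaros family, and of Il10, which encodes an anti-inflammatory cytokine. Il2ra, the gene of the IL-2 receptor alpha chain, had 1 Treg-specific region at 11651574 to 11651875 of chromosome 2 and 1 common region at 11653334 to 11653671, both inside the gene.

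**Figure D1:**
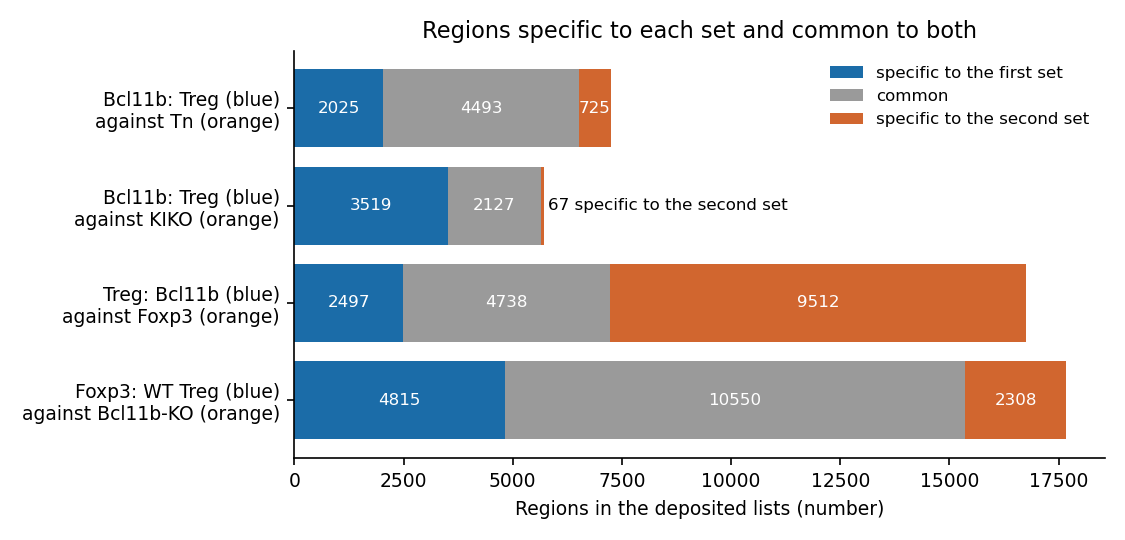
Number of regions (horizontal axis) in each class of the 4 comparisons, with blue for regions specific to the first set, grey for common regions and orange for regions specific to the second set. The KIKO comparison has 3519 regions specific to Treg and 67 specific to KIKO, and the Foxp3 comparison has 9512 regions specific to Foxp3.

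Rbpj, which encodes the transcriptional effector of Notch signalling, carried the most Treg-specific regions, 4, with none common. Csf1, a cytokine gene, and Actr10 carried 3 each with none common, and Atr, a DNA damage kinase gene, and Aadacl2fm2 carried 3 each beside 1 common region. Common regions were most numerous at Amz2 and Septin9, with 5 each, and at Actr3, Eapp and the immediate early gene Egr1, with 4 each. Tn-specific regions were most numerous at Tbc1d5, with 3, and at Ano6, Epha3, Fgf13 and Fgf18, with 2 each. All 3 regions of Satb1, a chromatin organiser gene, were common. Bcl11b itself had 1 common and 1 Tn-specific region. The Tn-specific one, at 107993095 of chromosome 12, was listed for Treg Bcl11b in the KIKO and Foxp3 comparisons, so the lists conflict there. No Bcl11b region of this comparison was assigned to Ikzf2, Gata3, Ifng or Il17a.

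Treg-specific regions lay away from gene ends. Of the 2025, 13.6% (12.2 to 15.2) were within 1 kb of a gene end, against 50.2% (48.7 to 51.6) of common regions (odds ratio 0.157, Fisher's exact test, adjusted p = 1.3e-189). The share was 33.2% among Tn-specific regions (odds ratio 0.495 against common, adjusted p = 1.8e-17 by the same exact test). None of the 12 gene lists took a share of the Treg-specific or Tn-specific regions that differed from its share of common regions after adjustment. The Treg signature held 12 of 2025 Treg-specific and 12 of 4493 common regions (odds ratio 2.23, 0.913 to 5.43, exact adjusted p = 0.44). Shared regions need care, because 956 common regions have the modal width of Treg Bcl11b, 198 bp, and 645 that of Tn, 226 bp.

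The comparison with KIKO cells asks which Bcl11b sites are kept in Treg cells without Foxp3. Most were listed as lost. Of 5646 Bcl11b regions on the WT side, 3519 were specific to WT Treg and 2127 (37.7%, 36.4 to 38.9) were common, while 67 were KIKO-specific. The Foxp3 region, both Il2ra regions, the Ctla4 region and the Ikzf4 region were lost. The 3 Satb1 regions, common with Tn cells, were lost as well, whereas the Il10 region at 131025849 to 131026132 of chromosome 1 was common. Bcl11b had 1 lost and 1 common region, the common one being that listed as Tn-specific in the Tn comparison.

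Egr1, Gnas, Rbpj and Slain1 each lost 4 regions and had none in common, and Amz2 lost 4 and kept 1. Gnas encodes the stimulatory G protein alpha subunit. Common regions were most numerous at B4galt5 and Lfng, a glycosyltransferase gene of the Notch pathway, with 3 each, and Adnp and Akna had 2 each. KIKO-specific regions were single, at genes that include Aasdhppt, Apbb2, Cenpw and Cerkl. Within 1 kb of a gene end lay 29.7% of lost, 50.4% of common and 10.4% of KIKO-specific regions (exact adjusted p = 9.2e-54 for lost and 1.1e-11 for KIKO-specific, each against common). No gene list differed in share between lost and common regions after adjustment. The naive and T lineage list held 24 lost and 8 common regions (odds ratio 1.82, 0.789 to 4.69, exact adjusted p = 0.59).

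Treg-specific Bcl11b regions were also listed as lost more often than those common with Tn. Loss in KIKO cells reached 86.7% (1756 of 2025) of Treg-specific regions and 52.8% (1754 of 3325) of regions common with Tn (odds ratio 5.85, 5.05 to 6.79, exact p = 4.1e-154). This cross-classification was chosen after the lists were seen. Both classes come from comparisons with the same WT Treg Bcl11b set, so a region called weakly or by chance in that set falls in both, and the odds ratio this alone would give was not computed. Among regions wider than 276 bp, the largest modal width of a set, 78.4% (149 of 190) of Treg-specific regions and 45.9% (872 of 1898) of those common with Tn were lost (odds ratio 4.27, 2.97 to 6.27, exact p = 3.5e-18). The small number of KIKO-specific regions means that nearly every difference runs one way, and the lists carry no measure of how well each immunoprecipitation worked.

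The comparison of the 2 factors in WT Treg cells asks how far their sites coincide. Bcl11b regions lay mostly where Foxp3 was also listed. Of 7235 Bcl11b regions, 4738 (65.5%, 64.4 to 66.6) were common with Foxp3, against a mean of 24.0 and a maximum of 40 over 1000 circular shifts (permutation p = 0.001, the smallest that 1000 shifts can give). Such shifts do not keep nearness to gene ends, which held for 37.9% of all regions and a mean of 3.20% after shifting. The shifts alone therefore cannot tell binding at the same sites from a shared preference for gene ends. However, 1213 shared regions that were also on the Treg side of the Tn comparison lay over 1 kb from a gene end. That is more than the maximum of 40 that shifting gave for all regions, and argues against gene ends as the source for these. Other shared preferences of the 2 factors were not tested. The Foxp3 set was larger, and 33.2% (32.5 to 34.0) of its 14250 regions were common with Bcl11b. Not all shared regions were listed for Treg Bcl11b elsewhere. Of the 4738, 2903 were on the Treg side of the Tn comparison and 2746 on that of the KIKO comparison. Of the 2497 Bcl11b-only regions, 2495 and 2497 were. The shared percent therefore depends on which comparison gives the Treg Bcl11b set. The Foxp3 gene region, 4 of 6 regions of Il2ra, 3 of 4 of Ctla4, 2 of 3 of Ikzf4, 2 of 6 of Il10 and all 4 of Bcl11b were shared. Some of these were not listed in the Tn or KIKO comparison, so only this comparison places Bcl11b there. They were Il2ra at 11634983 and 11642520, Ctla4 at 60898537 and 60908846, and Il10 at 131010549. The others were both shared Ikzf4 regions and Bcl11b at 108001935 and 108004049. The 5 regions of Ikzf2, another Ikaros family gene of Treg cells, and the 2 regions each of Gata3 and Ifng were listed for Foxp3 only.

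**Figure D2:**
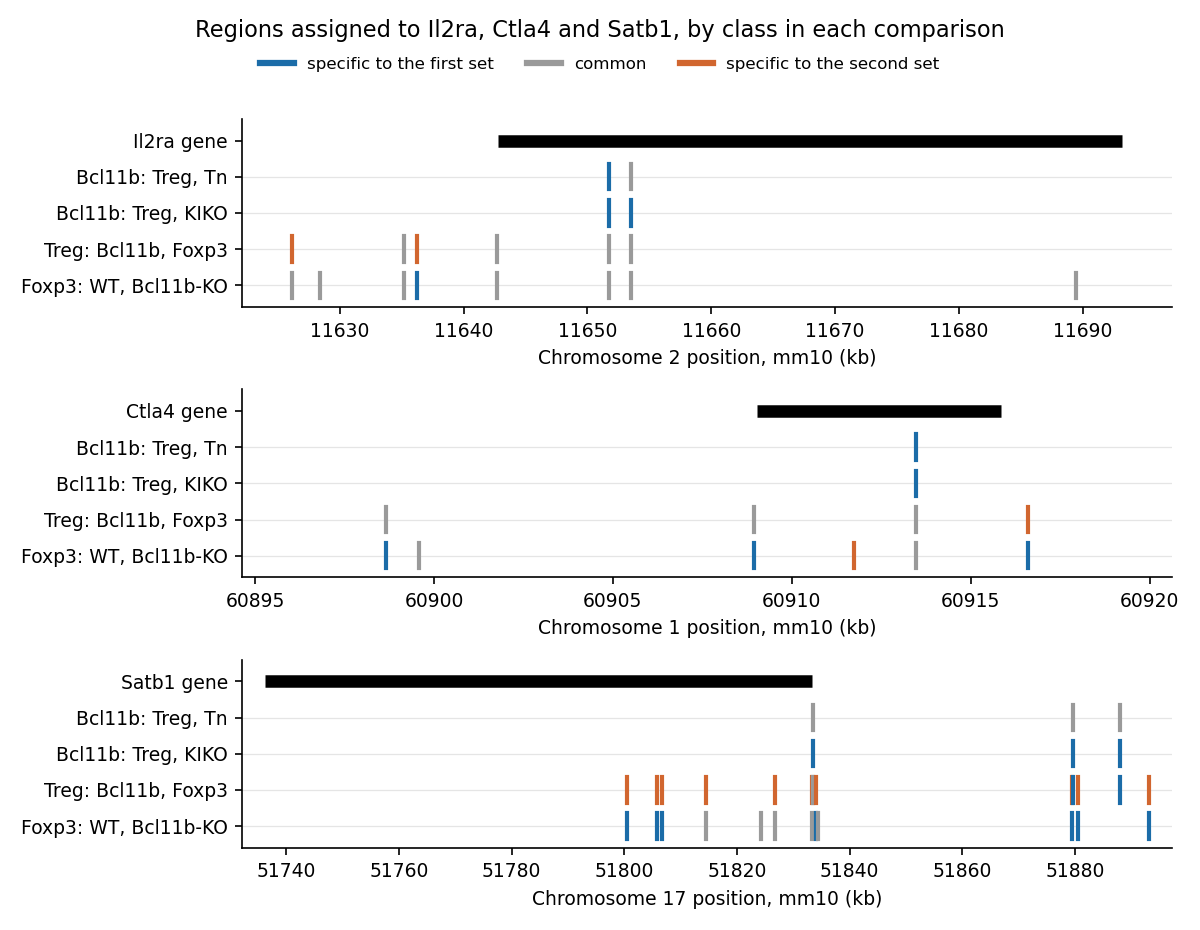
Regions assigned to Il2ra, Ctla4 and Satb1 along the chromosome (horizontal axis, mm10 position in kb), drawn as ticks at the region centres, with 1 row per comparison, blue and orange for regions specific to the first and second set, grey for common regions and a black bar for the gene. Of the 12 Satb1 regions listed in the comparison of WT and Bcl11b-KO Foxp3, 7 are blue and 5 grey.

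Foxp1, a forkhead gene, carried 14 Foxp3-only regions and 1 shared one, and Satb1 carried 10 Foxp3-only regions, 1 shared and 2 with Bcl11b only. Ubac2 and Zfp281 followed with 9 Foxp3-only regions each and Igf2r with 8. Shared regions were most numerous at Amz2, with 8, Rap1b, with 7, and Akna, St6gal1 and Stat5b, with 6 each; Stat5b encodes a mediator of IL-2 signalling. Bcl11b-only regions were most numerous at Hbs1l and Slain1, with 4 each, and at Aadacl2fm2, Acin1 and Actr10, with 3 each. Gene ends were within 1 kb of 54.1% of shared, 42.2% of Foxp3-only and 13.6% of Bcl11b-only regions (exact adjusted p = 8.0e-41 and 1.1e-267 against shared).

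Regions at genes of 3 lists were rarer among the Bcl11b-only than among the shared regions. The Treg signature took 4 of 2497 Bcl11b-only and 33 of 4738 shared regions (odds ratio 0.229, 0.0588 to 0.644, exact adjusted p = 0.036), with Cd83, Icos, Il10 and Il2ra holding no Bcl11b-only region. Chemokine receptors and homing genes took 3 and 28 (odds ratio 0.202, exact adjusted p = 0.037), the 28 including 5 at Ccr7, 3 at Itga4 and 2 each at Cxcr4 and Ccr9. The IL-2 and STAT5 list took 4 and 32 (odds ratio 0.236, exact adjusted p = 0.037), and also fewer of the 9512 Foxp3-only regions, 24 (odds ratio 0.372, 0.209 to 0.653, exact adjusted p = 0.014). Of its members, Mcl1 had 3 shared and 2 Foxp3-only regions, and Bcl2 had 2 Bcl11b-only and 3 Foxp3-only regions. Lists that did not pass had odds ratios of similar size, at 0.291 for housekeeping genes (2 and 13 regions) and for suppressive mediators and inhibitory receptors (2 and 13), each with an exact adjusted p = 0.48. The values were 0.344 for T helper effector, 0.447 for TCR signalling and 0.547 for naive and T lineage genes (exact adjusted p = 0.63, 0.26 and 0.48). With genes taken as their body and 10 kb to each side, the 3 Bcl11b-only calls ended (exact adjusted p = 0.083, 0.11 and 0.075). Over the 4 comparisons, 6 of 96 such tests were called, and 13 had an unadjusted exact p under 0.05.

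Bcl11b regions shared with Foxp3 were listed more often in the other cells than Bcl11b-only regions. Of Bcl11b regions shared with Foxp3, 11.9% (346 of 2903) were Treg-specific against Tn, compared with 66.8% (1666 of 2495) of Bcl11b-only regions (odds ratio 0.0674, 0.0584 to 0.0776; the Fisher's exact p is too small for the software to represent). Loss in KIKO cells was 52.5% (1442 of 2746) for shared and 80.5% (2009 of 2497) for Bcl11b-only regions (odds ratio 0.269, 0.237 to 0.305, exact p = 1.7e-103). Both tests leave out regions not on the Treg side of the Tn or KIKO comparison. They keep 2903 and 2746 of the 4738 shared regions, but 2495 and 2497 of the 2497 Bcl11b-only ones. Both odds ratios thus hold only for the regions kept. Counted over all 4738 shared and 2497 Bcl11b-only regions, 1304 and 488 were common with KIKO. Among regions wider than 276 bp, the largest modal width of a set, the odds ratio of Treg specificity was 0.330 (0.194 to 0.585, exact p = 1.0e-04). The difference in loss was no longer detected there, at 48.0% of shared and 54.5% of Bcl11b-only regions (odds ratio 0.770, 0.501 to 1.18, exact p = 0.22). The Foxp3, Tn and KIKO classes share the WT Treg Bcl11b set, so a region called in that set alone is Bcl11b-only, Treg-specific and lost at once, and the odds ratios this alone would give were not computed. Among regions listed as common with KIKO, the odds ratio of Treg specificity was 0.0669 (0.0478 to 0.0926, exact p = 1.7e-77). That of loss among regions listed as common with Tn was 0.490 (0.413 to 0.579, exact p = 8.9e-18). These common lists hold 538 and 956 regions of the modal width of Treg Bcl11b. It is therefore open whether the restriction leaves out regions called in that set alone.

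**Figure D3:**
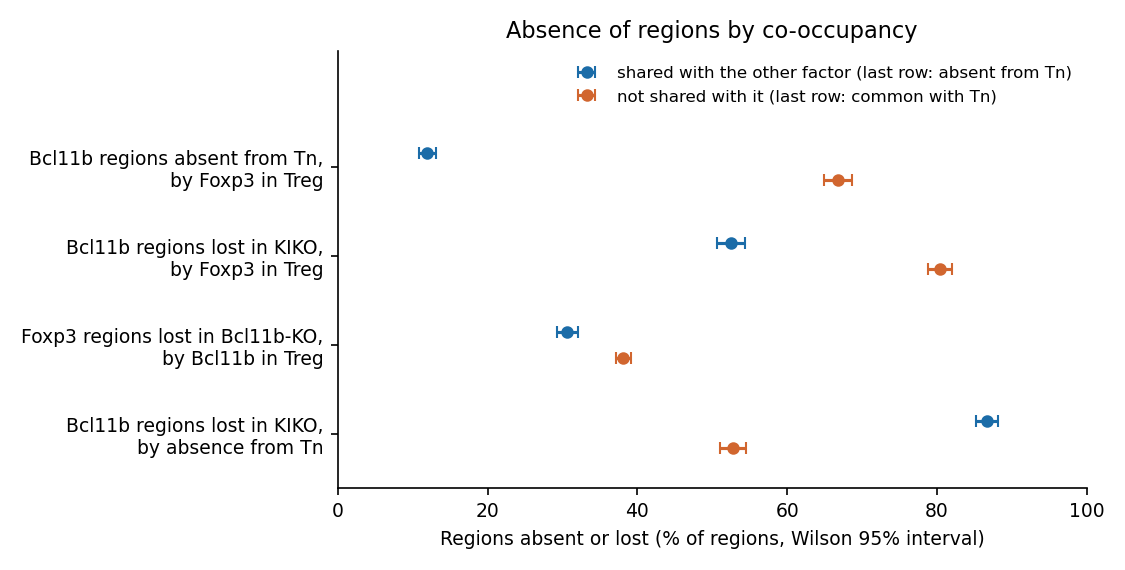
Percent of regions absent or lost (horizontal axis) with Wilson 95% intervals, blue for regions shared with the other factor and orange for regions not shared; in the last row blue stands for regions absent from Tn and orange for those common with Tn. Among regions on the Treg side of both comparisons, shared Bcl11b regions were Treg-specific in 11.9% and Bcl11b-only regions in 66.8%.

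The comparison of Foxp3 in WT and Bcl11b-KO Treg cells asks how Foxp3 sites change without Bcl11b. Most Foxp3 regions were common. Of 15365 WT regions, 10550 (68.7%, 67.9 to 69.4) were common and 4815 were lost, while 2308 were KO-specific. Foxp1 lost 12 regions and kept 5, Satb1 lost 7 and kept 5, and neither had a KO-specific region. KO-specific regions were most numerous at Klrg1, an inhibitory lectin-like receptor gene, at Bhlhe40, a transcription factor gene, and at Litaf, Extl3 and Arhgef3, with 5 each. The region in Foxp3 was common, as were 7 of 8 regions of Il2ra.

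Ubac2 lost 8 regions, Zfp281 7 and D16Ertd472e 6. Ikzf2 lost 4 and kept 2, Ctla4 lost 3, kept 2 and had 1 KO-specific region, and Ikzf4 lost 2, kept 1 and had 1 KO-specific region. Il10 had 1 lost, 4 common and 3 KO-specific regions. Its KO-specific regions at 131022582 and 131025849 were listed for WT Foxp3 in the comparison with Bcl11b, so the lists conflict there. The Il17a gene, which encodes an inflammatory cytokine, had a single region, KO-specific, 6.16 kb from the gene at 20740523 to 20740798 of chromosome 1. Ifng lost 2 of 3 regions and Gata3 1 of 3, and Bcl11b lost 2 of 4. Common regions were most numerous at Rap1b, with 11, Arhgap25, with 9, and Mgat4a, Septin9 and St6gal1, with 8 each. KO-specific regions lay within 1 kb of a gene end in 14.2%, lost regions in 42.9% and common regions in 47.8% (exact adjusted p = 7.2e-216 and 1.9e-08 against common).

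Naive and T lineage genes took a larger share of the lost regions, 58 of 4815 (1.20%), than of the common ones, 68 of 10550 (0.645%; odds ratio 1.88, 1.3 to 2.71, exact adjusted p = 0.021). Beside Foxp1 and Satb1, Ccr7 lost 5 regions and kept 2, and Bach2, a repressor gene of naive T cells, lost 2 and kept 4. The call ended with gene bodies extended by 10 kb (odds ratio 1.69, exact adjusted p = 0.10) and among regions over 1 kb from a gene end (odds ratio 1.67, exact adjusted p = 0.11). Markers of CD8 T and NK cells took 9 of 2308 KO-specific regions (0.390%) and 2 of 10550 common ones (odds ratio 20.6, 4.27 to 196, exact adjusted p = 7.1e-04). The 9 regions fell at 4 of the 12 marker genes: 3 at Ccl5, a chemokine gene, 3 at Klrk1 and 2 at Klrb1c, both genes of NK cell receptors, and 1 at Nkg7, a cytotoxic granule gene. The Klrk1 regions lay between 129608402 and 129624128 and the Klrb1c regions between 128788501 and 128796641 of chromosome 6. Not all were absent from WT Foxp3 in every list. The Klrb1c region at 128796366, the Klrk1 region at 129608402 and the Ccl5 region at 83550173 were listed for WT Foxp3 in the comparison with Bcl11b. Prf1 and Eomes had 1 common region each. Nkg7 and Prf1 were named after their values were seen.

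Markers of other cell types also took more of the KO-specific than of the common regions, without passing the adjusted threshold. B cell markers held 4 against 3 (odds ratio 6.10, 1.03 to 41.7, exact adjusted p = 0.22), and myeloid markers 6 against 5 (odds ratio 5.5, 1.40 to 22.8, exact adjusted p = 0.081). Suppressive mediators and inhibitory receptors held 15 against 26 (odds ratio 2.65, 1.3 to 5.20, exact adjusted p = 0.053), and the Treg signature 22 against 58 (odds ratio 1.74, 1.01 to 2.90, exact adjusted p = 0.31). The lost and KO-specific lists were also set against each other, a test chosen after the lists were seen and adjusted over 48 tests of the 4 comparisons. Naive and T lineage genes took 1.20% of lost and 0.433% of KO-specific regions (odds ratio 2.80, 1.42 to 6.16, exact adjusted p = 0.034), and T helper effector genes 0.228% and 0.737% (odds ratio 0.309, 0.130 to 0.7, exact adjusted p = 0.034). In the tests planned for the T helper list, against common regions, neither the lost (odds ratio 0.512, exact adjusted p = 0.34) nor the KO-specific regions (1.66, exact adjusted p = 0.48) passed. CD8 and NK markers took 0 of 4815 lost regions against the 9 KO-specific ones (exact adjusted p = 0.0019).

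Over all regions, Foxp3 regions shared with Bcl11b were listed as lost less often than the other Foxp3 regions when Bcl11b was absent, 30.6% (1253 of 4094) against 38.1% (3544 of 9293; odds ratio 0.716, 0.661 to 0.774, exact p = 3.8e-17). The direction turned among regions wider than 276 bp, where 23.2% of shared and 15.6% of unshared regions were lost (odds ratio 1.64, 1.43 to 1.88, exact p = 4.2e-13). Both classes come from comparisons with the same WT Treg Foxp3 set, so a region called weakly or by chance in that set is unshared and lost at once, and the odds ratio this alone would give was not computed. Width went with the number of sets that listed a region: 5.88% of the 7376 regions listed in 1 set and 89.0% of the 846 listed in all 5 were wider than 276 bp.

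Of the 12 gene lists, naive and T lineage genes and chemokine receptors and homing genes carried regions more often than matched random lists in all 5 sets, with the Treg Bcl11b set taken as the 5181 regions in all 3 comparisons and WT Foxp3 as the 13387 in both. Random lists were matched on genome length and not on expression. Housekeeping genes stood at 2.09 times the matched mean in Treg, 2.29 in Tn and 3.04 in KIKO. For Foxp3 they stood at 1.88 in WT and 2.21 in Bcl11b-KO cells. An excess was therefore not told apart from that of expressed genes in general. Of 26 naive and T lineage genes, 17 had a Bcl11b region in Treg (2.94 times the mean of matched random lists, permutation adjusted p = 9.0e-04), 20 in Tn (3.54 times, p = 9.0e-04 by the same permutation test) and 8 in KIKO (3.06 times, permutation adjusted p = 0.014, and 0.077 with gene bodies extended by 10 kb), with Runx1, S1pr1, Satb1 and Tcf7 holding 3 regions each in Treg. Foxp3 regions reached 24 of these genes in WT and 25 in Bcl11b-KO Treg cells. TCR signalling genes were occupied by Bcl11b at 16 of 30 in Treg and 24 of 30 in Tn cells (permutation adjusted p = 9.0e-04 for both), among them Rel and Themis with 3 regions each in Treg, and by Foxp3 at all 30 in WT Treg. The excess was 2.51 times the matched mean in Treg. Treg counts are not like for like with Tn or KIKO counts. The Treg set needs a listing in all 3 comparisons, the others only in their own. WT and Bcl11b-KO Foxp3 counts differ likewise, since the WT set needs a listing in both comparisons. In the Tn comparison, regions common to Treg and Tn reached 18 of the 26 naive and T lineage genes and 23 of the 30 TCR signalling genes. In KIKO cells 6 of the 30 had a Bcl11b region, 2.01 times the matched mean (permutation adjusted p = 0.25), in a smaller set that reached 2044 genes against 4302 in Treg; the difference was not tested.

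The Treg signature was occupied by Bcl11b at 16 of 31 genes in Treg (2.5 times, permutation adjusted p = 0.0014), led by Tigit with 3 regions, at 10 in Tn (1.55 times, permutation adjusted p = 0.31) and at 5 in KIKO (1.69 times, permutation adjusted p = 0.51). Foxp3 reached 28 in WT and 27 in Bcl11b-KO cells (2.29 and 2.34 times, permutation adjusted p = 9.0e-04 for both), with 6 regions each at Cd83 and Il2ra in WT. IL-2 and STAT5 genes had a Bcl11b region at 10 of 16 in Treg, 9 in Tn and 5 in KIKO (3.02, 2.71 and 3.18 times, permutation adjusted p = 0.0025, 0.0076 and 0.073). They had a Foxp3 region at all 16 in WT and 13 in Bcl11b-KO cells. Stat5b had 9 regions in WT, and Il2ra and Stat5b had 7 each in Bcl11b-KO cells. Of the chemokine receptors and homing genes, 11 of 20 were bound by Bcl11b in Treg, 12 in Tn and 6 in KIKO, with Cxcr5 first at 4 regions in Treg (permutation adjusted p = 0.003, 0.0014 and 0.038). Assignment to the nearest gene end ended the calls in Treg and KIKO (permutation adjusted p = 0.067 and 0.15), and extended gene bodies the one in KIKO (permutation adjusted p = 0.30). Foxp3 reached 16 of the 20 in WT and 18 in Bcl11b-KO cells (permutation adjusted p = 9.0e-04 for both).

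T helper effector genes had a Bcl11b region at 6 of 29 in Treg, 0.966 times the matched mean (permutation adjusted p of 1), and 1.05 times the mean without matching. Foxp3 reached 17 of them in WT (1.45 times, permutation adjusted p = 0.13) and 25 in Bcl11b-KO Treg (2.25 times, permutation adjusted p = 9.0e-04), where Batf had 7 regions, Rora and Stat4 6 each and Csf2 4; the difference between these 2 occupancies was not tested. Suppressive mediators and inhibitory receptors had a Foxp3 region at 12 of 17 in WT and 15 in Bcl11b-KO cells (permutation adjusted p = 0.039 and 0.0014), with 4 regions at Pdcd1 in WT and 6 in Bcl11b-KO cells, and a Bcl11b region at 7 in Treg (permutation adjusted p = 0.14). The call in WT ended with extended gene bodies (permutation adjusted p = 0.089). For both lists the WT Foxp3 count needs a listing in both comparisons, and the Bcl11b-KO count only in its own. In the Bcl11b-KO comparison alone, regions common to WT and Bcl11b-KO reached 18 of the 29 T helper effector genes. They reached 13 of the 17 suppressive mediators and inhibitory receptors. Lost regions reached 7 and 11, which may be the same genes. Housekeeping genes passed in both Foxp3 sets, at 13 and 14 of 20 (permutation adjusted p = 0.021 and 0.0046), and had a Bcl11b region at 7 in Treg, 8 in Tn and 5 in KIKO (2.09, 2.29 and 3.04 times, permutation adjusted p = 0.13, 0.059 and 0.079). The values in Treg and Tn passed with extended gene bodies (permutation adjusted p = 0.014 and 0.021).

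No B cell, myeloid or CD8 and NK list passed in any set. Neural genes had a Foxp3 region at 2 of 20 in WT Treg, 0.255 times the matched mean (permutation adjusted p = 0.023), with 6 regions at Mbp and 1 at Gad1. That call ended with extended gene bodies and with the nearest gene end (permutation adjusted p = 0.11 and 0.099). For WT Foxp3, B cell markers were reached at 4 of 15, myeloid markers at 4 of 17 and CD8 and NK markers at 2 of 12, and for Bcl11b-KO Foxp3 at 6, 5 and 6 (permutation adjusted p between 0.35 and 0.94). Bcl11b in Treg reached 2, 5 and 0 of them and 5 of the 20 neural genes (permutation adjusted p between 0.26 and 0.96). In all, 27 of 60 tests were called, and 30 had an unadjusted permutation p under 0.05.

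**Figure D4:**
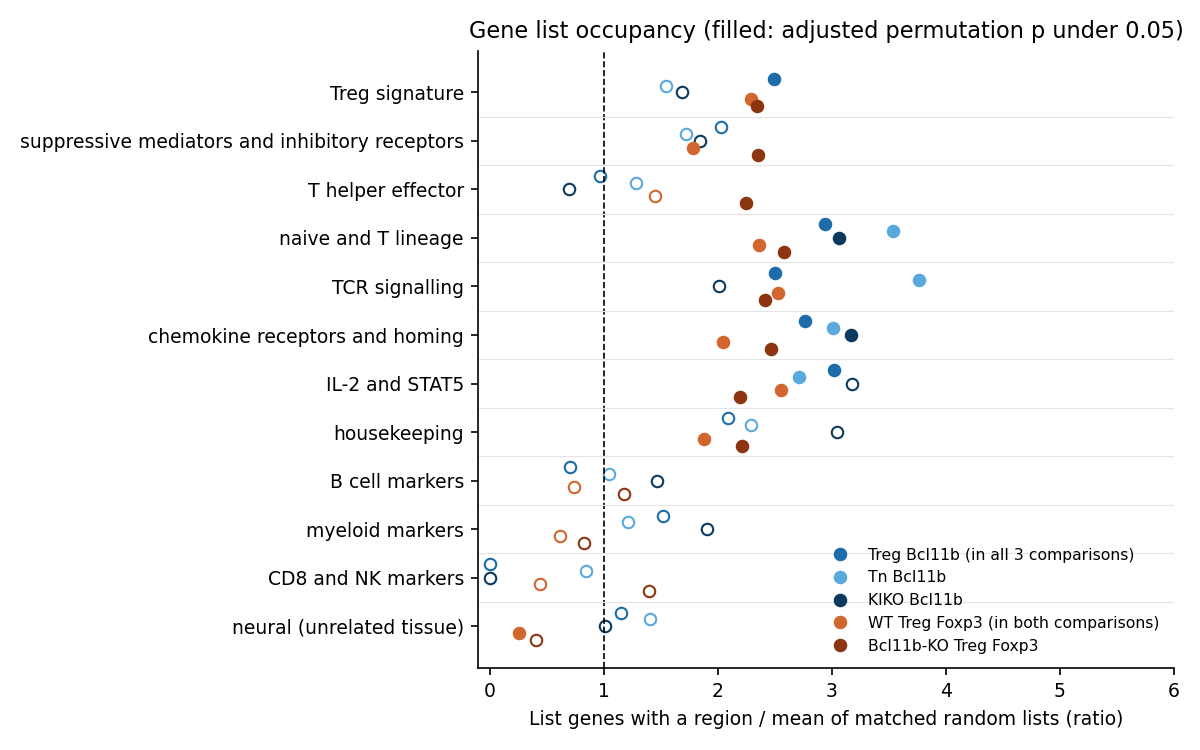
Ratio of list genes with a region to the mean of random lists matched on the length of genome nearest each gene (horizontal axis), for the 12 gene lists and 5 region sets, with filled points for an adjusted permutation p under 0.05 and a dashed line at 1. Naive and T lineage genes are filled in all 5 sets, and no B cell, myeloid or CD8 and NK list is filled.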

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

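The restrictions by width or by class in another comparison, the single-set widths, repeated rows, the nearest gene end and the lists far from gene ends were chosen after seeing the data. No paired analysis was possible because the lists are per group and carry no replicate, and for the same reason no replicate could be left out. Not run were the restriction to peaks of higher score and the Mantel-Haenszel, motif and score alternatives, which need a score or a genome sequence. An overlap of 1 bp and centres within 100 bp give the main values by construction, since regions never overlap, and say nothing about stability. Counting regions within 500 bp as shared moved the common share from 65.5% to 67.0% for Bcl11b with Foxp3 and from 68.7% to 71.5% for WT with Bcl11b-KO Foxp3. Leaving out common regions of a single-set width lowered the common share to 58.8% (Tn), 28.3% (KIKO), 59.2% (Foxp3) and 50.3% (Bcl11b-KO), by construction, since it removes common regions alone. Among regions wider than 276 bp the odds ratio of loss in KIKO by Foxp3 was 0.770 (p = 0.22, Fisher's exact test) and that of loss in Bcl11b-KO by Bcl11b reversed to 1.64. Width went with the number of sets that listed a region, so this restriction is not independent of the classes compared, and the cause of the change was not tested. Over 1 kb from a gene end these odds ratios were 0.379 and 0.617. The odds ratio of Treg specificity by Foxp3 stayed between 0.0669 and 0.330 over its alternatives. Gene bodies with 10 kb on each side left 2 of the 6 share-by-class calls, and the cause was not tested. Over all alternatives, the 6 calls kept their direction, and 19 values passed the threshold and 5 fell short of it, 4 of those with gene bodies. Assignment to the nearest gene end made 7 calls, 6 of them shared with the main setting, and regions over 1 kb from a gene end made 6, with 5 shared. In the occupancy tests, 219 values kept direction and side of the threshold, 7 fell short of it and 4 newly passed it. Another 10 turned direction without passing in either setting, and the cause was not tested. These were, within 20 kb, T helper effector genes with Treg Bcl11b (1.00 times), and 1.05 times without matching. With gene bodies they were B cell markers with Treg Bcl11b (1.5) and myeloid markers with Bcl11b in Tn (0.94) and KIKO (0.962) and with Bcl11b-KO Foxp3 (1.16). With the nearest gene end they were neural genes with Bcl11b in Treg (0.967) and Tn (0.985) and B cell markers in Tn (0.706) and KIKO (0.743). The gene end odds ratios kept direction and threshold at 2.5 kb and with any annotated gene. Read depth is unknown, so a region listed as specific can reflect a shallower library on the other side.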

Other observations

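The odds ratio of loss over all regions was planned; the tests by width were chosen after the lists were seen, and those among regions common with Tn, on chromosome X and on marker genes only after the results were seen. Among the 5181 Bcl11b regions listed on the Treg side of all 3 comparisons, 1459 (28.2%) were Treg-specific against Tn, lost in KIKO and not shared with Foxp3. A further 1191 (23.0%) were common to Tn, KIKO and Foxp3, and 1149 (22.2%) were common with Tn, shared with Foxp3 and lost in KIKO. The pattern that would tie Treg specificity to Foxp3 at the same site, Treg-specific, lost and shared, covered 287 regions (5.54%). The regions of Il2ra at 11651574 and of Ctla4 at 60913292, and the region of Foxp3, belong to these 287. Others do not: the Ikzf4 region at 128657894 was Treg-specific and lost but not shared. The Il10 region at 131025849 was Treg-specific and shared but common with KIKO, and the Il2ra region at 11653334 was common with Tn.

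The B cell and myeloid marker regions of the KO-specific Foxp3 list fell at few genes. Blk held 2, and Btk and Cd22 1 each, all genes of B cells. Itgam held 3, Fcgr3 2 and Spi1 1 of the myeloid regions. The Cd22 region at 30887626, the Spi1 region at 91082960 and the Fcgr3 region at 171060363 were also listed for WT Foxp3 in the comparison with Bcl11b. These genes were named after their values were seen.

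Among regions on the Treg side of both comparisons, Foxp3-shared Bcl11b regions were lost less often in KIKO cells than Bcl11b-only regions (odds ratio 0.269). That this comes from regions called in 1 set only is in line with the odds ratio of 0.770 (0.501 to 1.18) among wider regions, and weaker signal in the KIKO libraries with the more frequent loss of Bcl11b-only regions of the modal width of Treg Bcl11b, 198 bp (odds ratio 3.63, 2.57 to 5.10). Both explanations stay open, since width also went with the number of sets that listed a region and is not independent of loss. That Foxp3 holds Bcl11b at the same site, the biological explanation in the design, would need shared regions to be lost more often. The odds ratio was instead 0.490 (0.413 to 0.579) among regions common with Tn. This subset was added after the wider regions had left the question undecided. It leaves out the Treg-specific regions, so it cannot decide whether Foxp3 holds Bcl11b at those. Of the Treg-specific regions, 287 shared ones were lost and 59 were common with KIKO, against 1459 and 207 Bcl11b-only ones, a difference not tested. Unequal signal may also hide such an effect.

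Chromosome X held few Bcl11b regions of Treg cells, 8 of 2497 Bcl11b-only (0.320%) against 275 of 9512 Foxp3-only regions (2.89%), and 8 of 2025 Treg-specific against 27 of 725 Tn-specific ones (3.72%). KO-specific Foxp3 regions were also sparse there, 18 of 2308 (0.780%) against 124 of 4815 lost ones (2.58%). The number of genes on the chromosome is the same for both factors and so could not give the odds ratio of 0.108 (0.0461 to 0.216), and regions called in 1 set are argued against as the source for Bcl11b regions as a whole, since 17 of 2866 Bcl11b regions wider than 276 bp, shared ones included, lay there against 66 of 3153 Foxp3-only ones of that width (odds ratio 0.279, 0.153 to 0.483). For Bcl11b-only regions this width test cannot decide, because 93.55% of them are 198 bp wide. A difference in sex between the mice of the groups cannot be told apart from the factor or genotype, because the labels of 0 samples state a sex. No biological explanation was tested.

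Regions at CD8 and NK marker genes in the KO-specific Foxp3 list are a candidate for follow-up. The position of KO-specific regions away from gene ends is argued against but not excluded as their source. Over 1 kb from a gene end the odds ratio against common regions was 16.7 (2.03 to 769), from 6 regions against 1. The 6 regions lay at Ccl5, Klrk1 and Klrb1c only and are not independent, so this interval can be too narrow. Cells of other types in the Bcl11b-KO sort may contribute, as B cell and myeloid markers together also took a larger share there, with an odds ratio of 4.46 (1.28 to 17.4), although the sort on CD4 and YFP would be meant to remove them. Such cells would also have to give regions in a Foxp3 precipitate, which was not tested. Foxp3 binding at genes of other lineages in Treg cells that lack Bcl11b is the biological alternative. The Klrb1c region at 128796366, the Klrk1 region at 129608402 and the Ccl5 region at 83550173 were also listed for WT Foxp3 in the comparison with Bcl11b. By that listing, Foxp3 calls there depend neither on the Bcl11b-KO sort nor on the lack of Bcl11b. For the other CD8 and NK marker regions, the lists hold no value that separates this alternative from cells of other types.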
